A study of Danio rerio with 2 samples.

How the data were processed

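RNA was extracted with a column kit from whole zebrafish larvae of an AB/TL background at 5 days post fertilization, and standard Illumina libraries were prepared, per the labels' protocols. Each genotype was represented by 1 library made from a pool of 20 larvae, 1 pool of wild-type siblings and 1 pool of lri35 mutants. The allele is spelled lir35 in the sample labels and lri35 in the series title. The labels do not say which gene it affects, so the targeted gene could not be used to check the labels. Whether RNA was selected for poly(A) tails is not given in the sources used here.

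The authors deposited a single table of 33733 rows, 1 per Ensembl gene ID, with a gene symbol, a region, a value for each library, and a test status, p-value and q-value for each row. The submitters' processing notes name CASAVA, Bowtie and the Zv9 genome build, without versions or roles. The tool that made the table, the gene annotation release and the treatment of reads that map to several places are not given in the sources used here. The column names, the test statuses and the values match the layout of a Cuffdiff table, and on that basis the deposited values were read as FPKM, fragments counted per gene, scaled to the length of the gene and to the number of mapped fragments. The unit is therefore inferred and no label states it. The authors' p-values and q-values were copied from the deposited table and never recomputed. The columns of log2 fold change and of the test statistic held spreadsheet errors and were not used. The table names its libraries in each row, with names ending in WT and MT, and these were matched to the wild-type and the mutant library. Coordinates are those of the deposited table, on Zv9. No Zv9 genome or annotation was used here, so exons, introns and UTRs are not given. Of the 33733 IDs, 21934 were found in a current gene name table.

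FPKM values depend on the gene length and on how shared reads were assigned, and near-identical genes or rows over the same region can trade values. Absolute depth is unknown. Relative depth was estimated from the 350 rows above 0 in both libraries with a mean of at most 0.3 FPKM. The ratio of mutant to wild-type FPKM in these rows had its mode at 0.804, which corresponds to about 1.24 times more counted fragments in the mutant library. Of these rows, 40.6% lay within 0.1 of that ratio on the log2 scale. Without counts, no counting interval or detection floor can be given for any value. An FPKM of 0 is described as listed at 0, since a failed estimate cannot be told from absence, and no fold is given against it.

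Rows sharing a symbol were summed, which left 29358 symbols, of which 765 had several rows. The difference between the 2 libraries was log2((mutant FPKM + 1)/(wild-type FPKM + 1)), with a pseudocount of 1 FPKM that shrinks the difference of low genes. Symbols with a mean over both libraries of at least 1 FPKM were kept, and a gene was called higher or lower when the difference reached 2-fold on this scale. Folds given for single genes are plain ratios of the deposited FPKM values. With 1 library per genotype there are no replicates, so no test across samples, no standard deviation and no p-value was computed, and every difference compares the 2 libraries and not the genotypes. Pool, library and genotype are confounded.

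A total of 41 gene lists covering tissues, cell types and stress or metabolic pathways was written down and matched by symbol. For each list, the median log2 difference of the members with a mean of at least 1 FPKM was ranked among the medians of 10000 random lists of the same size, drawn from the same of 20 bins of mean FPKM. This percentile describes these 2 libraries only. The lists, the 2-fold rule, the filters, the rule for named genes and the alternatives were fixed before the data were examined, except where an alternative is said to have been added later. Named genes carry an assigned symbol (not a clone or systematic name) and a mean of at least 5 FPKM. They are the 12 with the largest difference in each direction past 2-fold and, for each list, the 2 members with the highest difference, the 2 with the lowest and the 2 most abundant. Genes called in the authors' deposited table are named as well, and any other gene is said to have been chosen after its values were seen. The text prints only some of the members picked from the lists. Of the genes with the largest differences, 1 is not reported here, nor are the values of 1 list.

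The procedure was tested on simulated data, made from the 19112 measured genes of the mutant against wild-type comparison. Of 10 simulated lists with no shift, 0 had a median above the 97.5 percentile of random lists. With shifts of 0.5, 1 and 2 on the log2 scale, 10 of 10 lists did each time. The 2-fold rule recovered 13.0% of single genes shifted by 0.5, 48.5% of those shifted by 1 and 97.5% of those shifted by 2, and called 2.5% of unshifted genes higher. The simulated noise was resampled from the observed differences of genes of like mean FPKM, with random signs. The 2.5% therefore reflects the observed spread and is no rate of false calls. Simulated lists held genes drawn at random, so they do not show how lists of genes that vary together behave. Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter on low values, a mean of at least 5 FPKM, rescaling by the median ratio, the upper quartile or totals without the 50 most abundant genes, the highest row per symbol, fold rules of 1.5 and 4, and a q-value limit of 0.01 on the authors' deposited table. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.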

Results

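Gene expression was measured by RNA sequencing in whole zebrafish larvae at 5 days post fertilization, an age at which larvae have a functioning gut, liver, pancreas and retina. The series compared lri35 mutants with their wild-type siblings, with 1 library per genotype and 20 pooled larvae per library. There are no replicates, so every difference below compares the 2 libraries. The deposited FPKM values summed to 875340 in the wild-type library and 874244 in the mutant library. A value above 0 was listed for 22106 rows in wild type and 22504 in the mutant, and 19179 and 19107 rows reached 1 FPKM. The mutant library appeared about 1.24 times deeper from its low values, while absolute depth is unknown. The 10 most abundant rows held 15.3% of the FPKM in wild type and 17.0% in the mutant. The 13 mitochondrial protein-coding genes accounted for 11.2% and 13.6%.

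The comparison asked which genes differed in expression between mutant larvae and their siblings. Digestive enzyme genes of the exocrine pancreas were lower in the mutant library as a group, and so were the hemoglobins and other genes of red blood cells. Of 19112 genes with a mean of at least 1 FPKM, 548 were at least 2-fold higher and 596 at least 2-fold lower in the mutant library, 5.99% in all. Among the 1653 genes with a mean of at least 50 FPKM, 7 were higher and 34 lower, and the lower ones included many genes of pancreatic enzymes and globins. The median log2 difference over all 19112 genes was -0.01, and 95% of them lay between -1.10 and 1.06. Values of log2(FPKM + 1) correlated across genes with a Pearson r of 0.951, where genes are not independent replicates. Rescaling moved the median of all genes to at most 0.02.

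**Figure D1:**
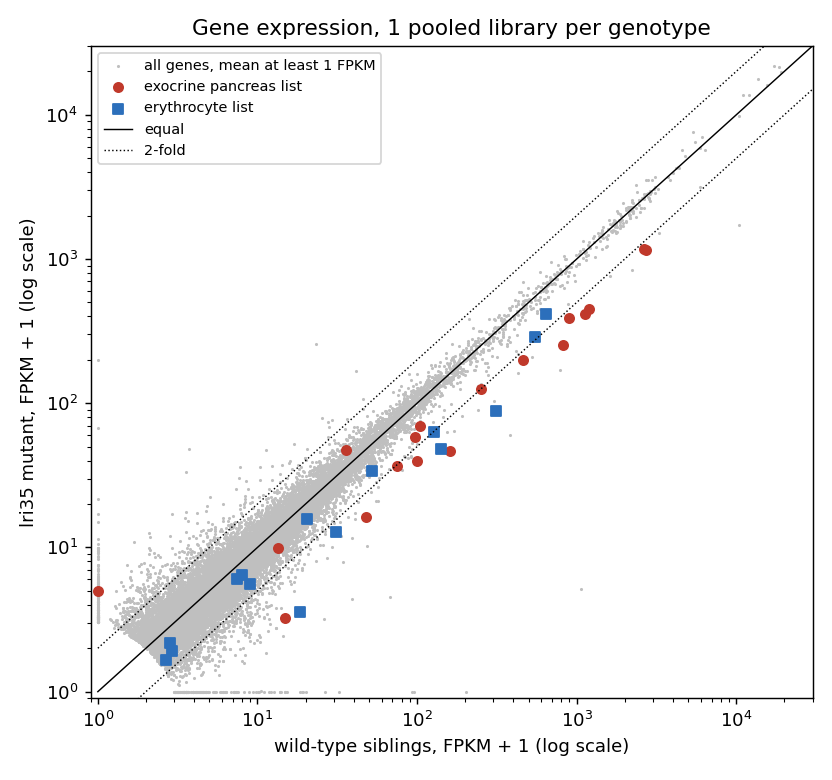
FPKM + 1 in the wild-type library (x axis, log scale) against the mutant library (y axis, log scale) for each gene with a mean of at least 1 FPKM (grey points), with the exocrine pancreas list (red circles) and the erythrocyte list (blue squares). The solid line marks equal values and the dotted lines 2-fold differences; 13 of the 18 exocrine genes and 5 of the 15 erythrocyte genes lie on or beyond the lower 2-fold line.

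Among single genes with an assigned symbol and a mean of at least 5 FPKM, the largest differences toward the mutant library included dhx57, a putative RNA helicase, at 2.59 FPKM in wild type and 32.1 in the mutant (12.4-fold). Also higher in the mutant library were traf3ip2l (6.78 to 35.2 FPKM, 5.19-fold), lepb, which encodes the hormone leptin b (1.83 to 11.0, 6.03-fold), and lmx1ba, a LIM homeobox gene (3.16 to 16.3, 5.15-fold). The coactivator gene crtc1b stood at 1.12 and 10.7 FPKM, vkorc1, whose region holds another gene, at 0.694 and 9.86, and COL18A1 (2 of 2) at 1.097 and 8.95. The synaptic gene rimbp2 stood at 2.72 and 46.8 FPKM over a pair of rows that share a region, so its value is uncertain. The small nuclear RNA U2 summed to 22.4 and 256 FPKM over 15 rows. With the highest row per symbol in place of the sum, the log2 difference went from 3.46 to 2.37 for U2 and from 3.68 to 5.52 for rimbp2. The symbols U4, SNORA23 and syt14a were listed at 0 in wild type and at 197, 20.8 and 14.03 FPKM in the mutant. U4 was summed over 30 rows, of which only 1 was above 0, and SNORA23 over 2 rows. Rows of U2, SNORA23 and SNORA79 likewise share their regions with other genes.

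In the other direction, the 7SK RNA gene rn7sk, whose product holds the elongation factor P-TEFb in an inactive complex, was 6.43-fold lower (381 to 59.25 FPKM). The cathepsin gene ctsbb was 5.20-fold lower (47.9 to 9.21) and CACNA2D1 (3 of 3), a calcium channel subunit gene, 9.34-fold lower (13.4 to 1.44), in a region that holds other genes, which were listed at 0. The heme synthesis gene alas2 was 6.80-fold lower (17.5 to 2.58), in a region it shares with ela2l. Another 7 of the 12 were listed at 0 in the mutant. Their wild-type values were 202 FPKM for SNORA79, 92.4 for U12, 25.4 for tomm5, 18.1 for fgf2, 17.5 for col15a1a, 13.98 for Telomerase-vert and 13.9 for mvdb. The regions of U12, col15a1a, Telomerase-vert and mvdb are short, from 30957394 to 30957584 on Zv9 chromosome 18 for mvdb. FPKM is scaled to length, so a few fragments there can give such values, and a loss in the mutant was not shown. In all, 24 genes with a mean of at least 5 FPKM were listed at 0 in one library. Of these 24, 18 were listed at 0 in the mutant and 6 in wild type.

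Digestive enzyme genes of pancreatic acinar cells were lower together in the mutant library. Of 18 measured members of the exocrine list, 13 were at least 2-fold lower, 1 was at least 2-fold higher and 4 lay within 2-fold. The median log2 difference was -1.19, a 2.28-fold lower level, below all 10000 random lists of matched expression (percentile 0). Trypsin (try) stood at 2719 FPKM in wild type and 1159 in the mutant (2.35-fold lower) and chymotrypsinogen (ctrb1) at 2624 and 1162 (2.26-fold lower). Pancreatic amylase amy2a was 3.50-fold lower (161 to 45.9 FPKM) and the secreted phospholipase gene pla2g1b 6.14-fold lower (13.9 to 2.26). The elastase gene ela3l was 3.22-fold lower (817 to 254 FPKM).

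Summed over the 18 genes, the enzymes took 1.22% of all FPKM in wild type and 0.512% in the mutant. The members nearest to or above equality were endou (12.5 to 8.85 FPKM) and rnasel3 (35.1 to 46.5 FPKM). The acinar transcription factor gene ptf1a, named here after its values were seen, was the member called higher, listed at 0 in wild type and at 4.01 FPKM in the mutant. Matching by Ensembl ID, a choice added after the data were seen, brought in 3 more members. These, named after their values were seen, were prss59.1 (2209 to 840 FPKM), prss59.2 (3266 to 1525) and sycn.1 (425 to 161), and the median over 21 members became -1.20. Several of these genes have close copies, and ctrb1 shares its region with zgc:136461 (788 to 170 FPKM, likewise named afterwards), so single values may be split between copies.

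**Figure D2:**
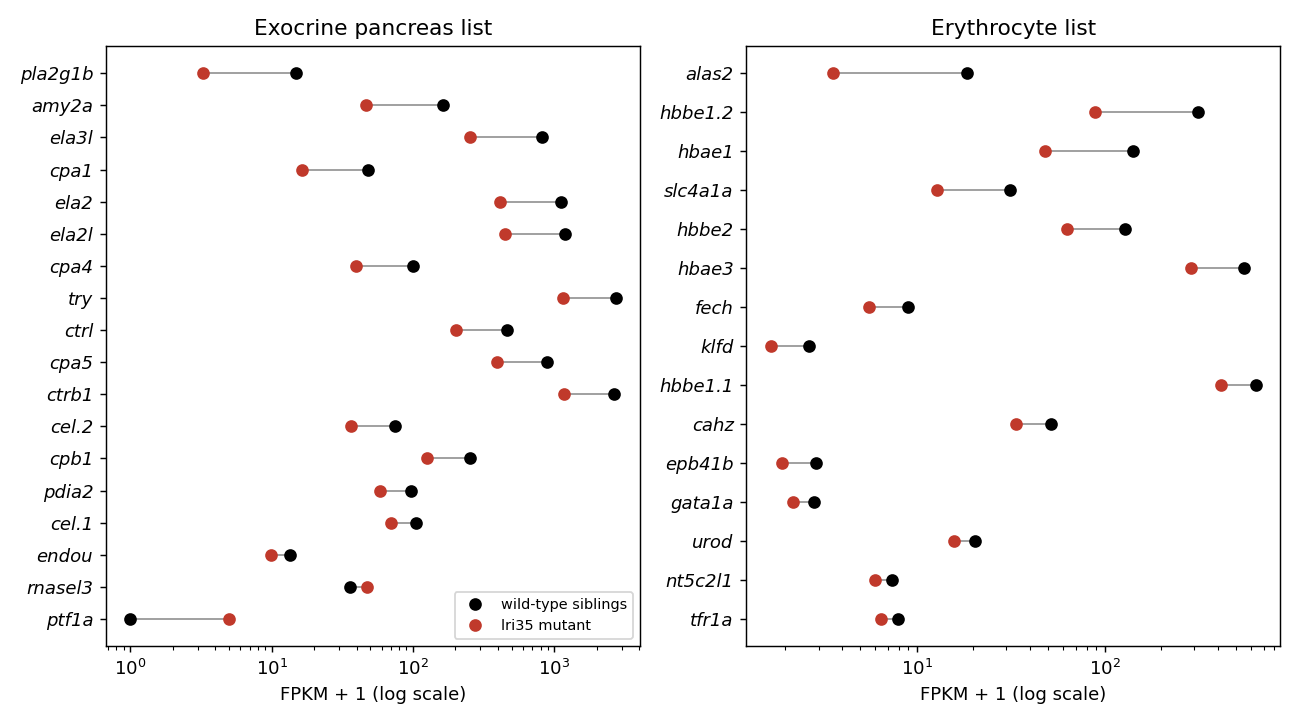
FPKM + 1 (x axis, log scale) in the wild-type library (black) and the mutant library (red) for each measured member of the exocrine pancreas list (left) and of the erythrocyte list (right), 1 library per genotype, with a line joining the 2 values. Trypsin (try) lies at 2719 FPKM in wild type and 1159 in the mutant, and all 15 erythrocyte genes matched by symbol have the lower value in the mutant.

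Genes of red blood cells were the next group. Of 15 measured members of the erythrocyte list, which were matched by symbol, 5 were at least 2-fold lower, 0 were at least 2-fold higher and all 15 lay below 0. The median log2 difference was -0.67, also below all random lists (percentile 0). The embryonic beta globin hbbe1.2 was 3.55-fold lower (311 to 87.6 FPKM), while the more abundant hbbe1.1 stood at 639 and 412 FPKM (1.55-fold lower) and hbae3 at 548 and 286 (1.92-fold lower). The members closest to equality were tfr1a, a transferrin receptor gene (6.94 to 5.48 FPKM), and nt5c2l1 (6.39 to 5.01). Summed over the list, FPKM was 1.96-fold lower in the mutant library. Matching by Ensembl ID added 1 member, the globin gene hbae5, which was higher in the mutant library (0.912 to 4.60 FPKM), so that 1 of 16 members was at least 2-fold higher and the median became -0.65. This match was chosen after the data were seen. Globin genes lie side by side as near-identical copies, and the files do not show how shared reads were assigned among them.

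The authors' deposited table tested 14574 rows and called 18 of them, 15 lower and 3 higher in the mutant. The rows it left untested had a mean of at most 4.97 FPKM. Of the genes named above for the largest differences in either direction, only rn7sk is among these 18. With 1 library per genotype, the p-values of the authors' deposited table compare these 2 libraries. All 18 stand in the authors' deposited table at the smallest p it holds, 5e-05, with a q of 0.0405. By gene identity, 9 of the 15 lower genes are digestive enzyme or zymogen granule genes. In the authors' deposited table these are ela3l, amy2a, cpa4, ela2, ela2l, ctrl, CELA1 (2 of 7), SYCN (1 of 2) and the amylase gene zgc:92137 (240 to 88.4 FPKM). The authors' deposited table also calls 3 globin genes lower, hbbe1.2, hbae1 and si:ch211-5k11.12, the last at 302 and 103 FPKM. The other 3 lower genes of the authors' deposited table are rn7sk, the cathepsin gene ctsl.1 (152 to 61.7 FPKM, 2.47-fold) and the astacin protease gene c6ast4 (526 to 209 FPKM, 2.52-fold). The 3 called higher in the authors' deposited table are si:ch73-39o22.3 (40.2 to 166 FPKM), C22H1orf53 (listed at 0 and at 8.49) and CRHR2, a receptor of corticotropin-releasing hormone family peptides (listed at 0 and at 4.56). At p under 0.05 before correction, the authors' deposited table holds 428 rows, 248 lower and 180 higher.

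Genes of the gut, liver and fuel metabolism were lower by smaller amounts. The enterocyte list had a median of -0.26 over 32 genes (percentile 0), with 26 below 0 but only 1 at least 2-fold lower and 1 at least 2-fold higher. The peptide transporter slc15a1b was 1.94-fold lower in the mutant library, while the chitinase chia.3 stood at 29.1 and 12.7 FPKM and tmigd1 at 2.60 and 8.83. The abundant apolipoprotein genes apoa1b and apoa1a were 1.09-fold lower and 1.15-fold higher in the mutant library. The fatty acid oxidation and fasting list had a median of -0.35 over 20 genes (percentile 0), none past 2-fold. In that list, the gluconeogenic genes pck1 and fbp1b stood at 420 and 295 FPKM and at 275 and 178 FPKM, while hadhaa, of mitochondrial fatty acid oxidation, was higher in the mutant library (14.9 to 20.3). The fatty acid synthesis list had a median of -0.17 (percentile 1.57), with me1 at 11.5 and 5.32 FPKM, acaca, the first enzyme of the pathway, at 20.8 and 10.5, and scdb at 26.6 and 40.4.

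Hepatocyte genes were lower by a small amount as a group. Of 44 measured, 3 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.15 (percentile 0.01). The cytochrome P450 genes cyp2ad2 (28.5 to 9.09 FPKM) and cyp3a65 (90.5 to 41.8) had the lowest differences, while the abundant apoa2 stood at 6125 and 7038 FPKM and rbp4, the plasma retinol carrier, at 1659 and 1529. The cholesterol synthesis list lay inside the random range, with a median of 0.10 over 22 genes (percentile 88.7).

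Hormone genes of the islet and gut went both ways. The islet and enteroendocrine hormone list had a median of 0.02 over 17 genes (percentile 59.4), and a median of -0.15 when a mean of at least 5 FPKM was required. Insulin (ins) stood at 86.7 FPKM in wild type and 77.3 in the mutant, and the glucagon genes gcga and gcgb at 20.6 and 24.0 and at 16.7 and 19.8. The gut hormone genes mlnl, which encodes a motilin-like peptide (10.6 to 1.65 FPKM), and cck (14.2 to 7.09) had the lowest differences of the list. The somatostatin gene sst3 was 1.59-fold lower (22.6 to 14.2 FPKM). In all, 3 members were at least 2-fold higher and 1 at least 2-fold lower. The higher ones were ghrl, which encodes ghrelin (1.12 to 6.60 FPKM), insl5a (2.56-fold higher) and insl5b (listed at 0 and at 5.25). These 3 and sst3 were named after their values were seen. The glucocorticoid and pituitary list had a median of -0.16 over 28 genes (percentile 2.16). Its lowest member was avp, the vasotocin gene (9.96 to 2.28 FPKM, 4.38-fold lower), and its highest were prl and socs3a.

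The cone, lens and neuron lists lay slightly below 0 and the rod list slightly above it. The cone list had a median of -0.19 over 24 genes (percentile 0.34). In that list the cone phosphodiesterase subunit gene pde6h stood at 969 and 707 FPKM, the ultraviolet opsin opn1sw1 at 1546 and 1376, and gngt2a at 43.3 and 64.9. The lens list had a median of -0.15 over 50 genes (percentile 0), with 41 below 0 and crystallins crybb1 and cryba4 at 1.18 and 1.16-fold lower. The neuron list had a median of -0.13 over 36 genes (percentile 0.38), none past 2-fold. Rod genes had a median of 0.07 (percentile 78.5), with rho, the rod opsin, at 587 and 541 FPKM. The circadian clock list had a median of -0.20 over 31 genes (percentile 0.01) and of -0.13 with a pseudocount of 5 FPKM, none past 2-fold at the main setting, with per1a at 7.29 and 4.33 FPKM and aanat2, of melatonin synthesis, at 7.91 and 5.31. The fast muscle list had a median of -0.08 over 35 genes (percentile 1), with the calcium release channel gene ryr1b 2.38-fold lower.

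Of 41 lists, 4 lay above and 12 below the central 95% of the medians of random lists. If genes varied independently, 2.05 would be expected outside. Genes of one tissue may vary together between any pools, and some lists share members. More lists may therefore fall outside without any effect of genotype. The ribosome biogenesis list was the highest, with a median of 0.17 over 52 genes (percentile 99.98) and 42 above 0, none past 2-fold. The nucleolar genes imp3 and nolc1 stood at 15.8 and 25.5 FPKM and at 14.2 and 21.6, and npm1a at 164 and 206. Ribosomal protein genes themselves had a median of 0.01 over 75 genes (percentile 33.9), and of 0.041 after rescaling to totals without the 50 most abundant genes. The proteasome list had a median of 0.15 over 32 genes (percentile 99.3), with 28 above 0, psmb6 at 54.4 and 73.8 FPKM and psme4b at 16.7 and 10.5. The epidermis list had a median of 0.14 (percentile 99.1), with the abundant icn at 1.39-fold and cyt1l at 1.51-fold higher, while krt17 was 1.61-fold lower. Nuclear genes of oxidative phosphorylation had a median of 0.08 over 64 genes (percentile 97.7), with ndufa5 at 137 and 193 FPKM.

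The stress lists given here lay inside the random range, with single genes that differed. The heat shock list had a median of 0.13 (percentile 97.2), with the collagen chaperone serpinh1b at 3.78 and 11.7 FPKM and dnaja1 at 3.19 and 7.46, while the abundant hspa8 and hsp90ab1 were 1.06 and 1.13-fold lower. The acute phase list had a median of 0.00 (percentile 44.3), with junba 2.61-fold and fos 2.08-fold higher and crp 1.81-fold lower. Medians were -0.04 for the unfolded protein response (percentile 21.2), 0.09 for the ATF4 response (percentile 88.4), -0.09 for oxidative stress (percentile 3.03), -0.01 for glycolysis and hypoxia (percentile 28.4) and -0.01 for lysosome and autophagy (percentile 29.3). In the DNA replication and cell cycle list the median was 0.02 over 53 genes (percentile 65.6), with pcna at 136 and 148 FPKM, rrm2 at 31.0 and 51.8 and ccna2 at 15.1 and 7.66.

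Other cell types differed little as groups. Medians were -0.05 for neutrophils and macrophages (percentile 30.0; 0.084 when a mean of at least 5 FPKM was required), 0.01 for endothelium (percentile 63.8), -0.04 for pronephros (percentile 38.3), 0.05 for ionocytes (percentile 72.5) and 0.06 for hair cells (percentile 66.7). They were 0.06 for cilia (percentile 86.8), 0.07 for cartilage and collagen (percentile 82.8), 0.07 for slow muscle and heart (percentile 78.7) and 0.12 for pigment cells (percentile 94.0). They were -0.11 for other retinal neurons and glia (percentile 8.72), -0.11 for myelin and glia (percentile 7.15) and -0.07 for retinal pigment epithelium (percentile 13.9). In the endothelium list fli1a stood at 19.1 and 10.9 FPKM, in the pigment cell list the pteridine synthesis gene gch2 at 121 and 182, and in the pronephros list the water channel gene aqp8b at 3.95 and 7.33. The neutrophil and macrophage list shares cpa5 (888 to 390 FPKM) with the exocrine list. Of the 41 lists, 38 had a median within 0.3 of 0 and 23 had no member past 2-fold.

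**Figure D3:**
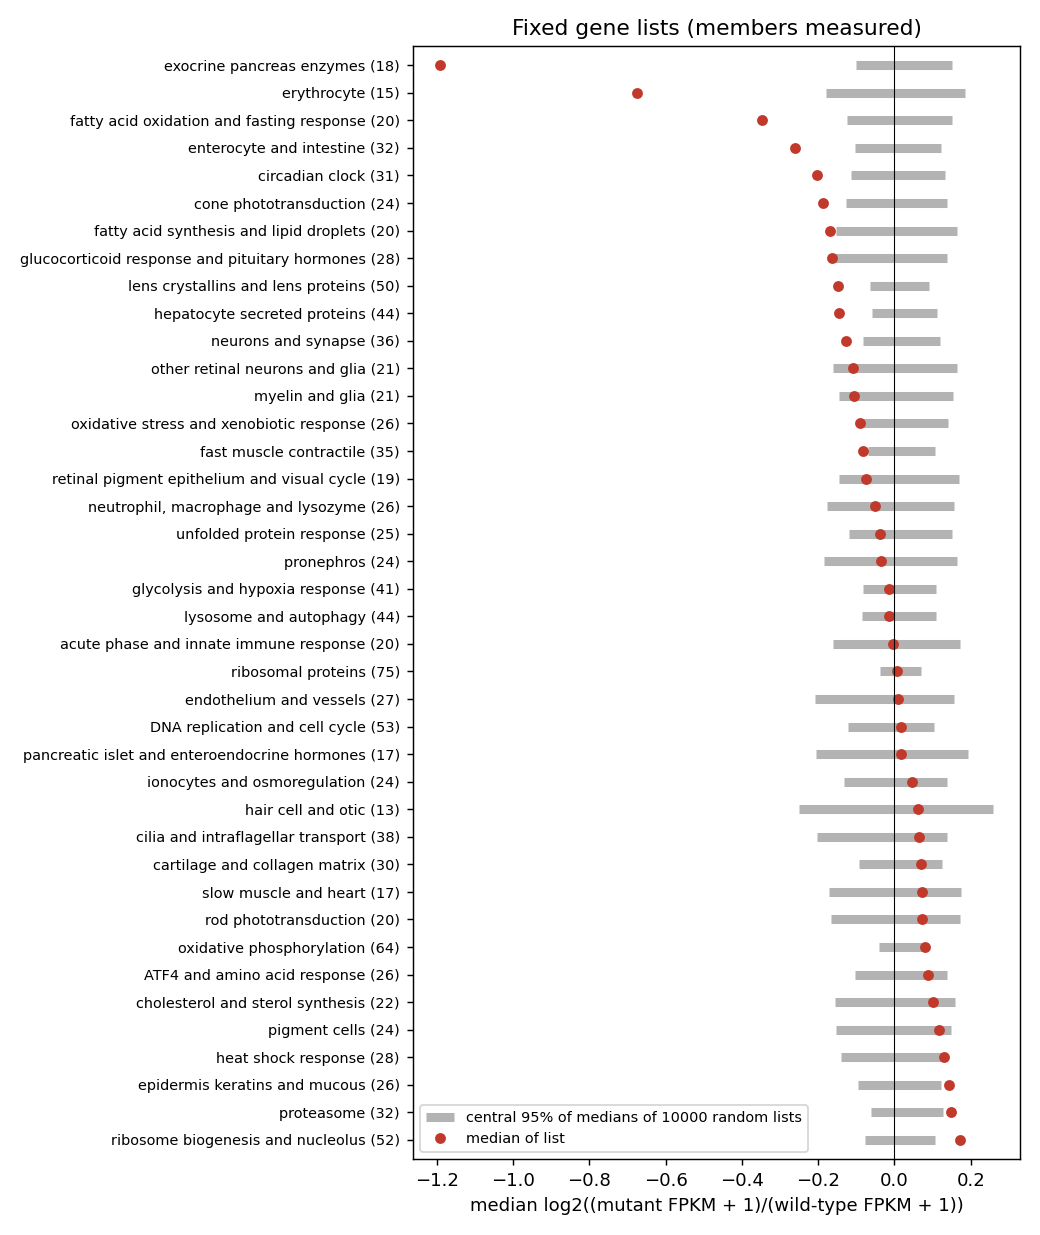
Median log2((mutant FPKM + 1)/(wild-type FPKM + 1)) of the gene lists (red points, number of measured members in brackets), with the central 95% of medians of 10000 random lists of matched size and expression (grey bars). The exocrine pancreas list at -1.19 and the erythrocyte list at -0.67 lie farthest from 0, and the ribosome biogenesis list is the highest at 0.17.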

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

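Of 370 list medians under alternatives, 360 moved by less than the spread of matched random lists, 10 moved by more and 0 of those outside the random range changed sign; the members matched by Ensembl ID, the erythrocyte list without alas2 and the counts without genes listed at 0 were chosen after seeing the data. The exocrine median stayed between -1.20 and -1.16. The erythrocyte median was -0.94 with a pseudocount of 0.1 FPKM, -0.56 with 5 FPKM and -0.82 with a mean of at least 5 FPKM. With a pseudocount of 5 FPKM, medians were -0.20 for enterocytes, -0.27 for fatty acid oxidation and -0.13 for the circadian clock. With a mean of at least 5 FPKM they were -0.15 for islet hormones and 0.084 for neutrophils and macrophages. With totals without the 50 most abundant genes they were 0.11 for oxidative phosphorylation and 0.041 for ribosomal proteins. A larger pseudocount shrinks the difference of low genes by construction; for the other moves the cause was not tested.

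Counts of single genes depended strongly on the settings. With pseudocounts of 0.1 and 5 FPKM, 927 and 91 genes were higher and 1049 and 124 lower. With a mean of at least 5 FPKM, which leaves fewer genes, 156 were higher and 197 lower. Fold rules of 1.5 and 4 gave 1523 and 109 higher and 1767 and 101 lower. Rescaling changed the median of all genes to at most 0.02. At a q under 0.01 the authors' deposited table calls 0 genes. All 18 calls stand at the smallest p that table holds, where q is 0.0405. No row could therefore pass the stricter limit, and the 0 does not rank the strength of the calls. Of 144 values of the named genes, 43 moved by more than the spread of genes of like abundance and 0 changed direction. Depth is known only as a ratio, so values near 1 FPKM have no stated precision.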

Other observations

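All gene groups and genes of this and the next paragraph were chosen after their values were seen. The 13 mitochondrial protein-coding genes were each higher in the mutant library, with a median log2 difference of 0.31 and a range from 0.03 for mt-nd6 to 0.37 for mt-nd2. Immediate early genes of the fos, jun and egr families, which neurons and injured tissue switch on within minutes of a stimulus, were above 0 for 12 of 15 members with a median of 0.58. In this set EGR4 (1 of 2) stood at 3.92 and 12.1 FPKM, junbb at 34.2 and 65.4, and fosb at 4.45 and 2.91. Subunits of RNA polymerase III were above 0 for 8 of 9 genes with a median of 0.35, led by polr3f at 5.71 and 10.7 FPKM. The hatching enzyme genes he1a and he1b, which are made by the hatching gland before the larva leaves the chorion, stood at 11.4 and 35.6 FPKM and at 1.12 and 8.60 FPKM. Another astacin protease, c6ast3, was lower in the mutant library (22.2 to 7.01 FPKM), as was c6ast4.

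Of the genes with a systematic name, si:dkey-15h8.16 stood at 1056 FPKM in wild type and 4.15 in the mutant, on Zv9 chromosome 22 from 3123349 to 3131026. The authors' deposited table does not call si:dkey-15h8.16. On Zv9 chromosome 7 from 75311744 to 76849489, a stretch bounded by genes picked for being lower, 28 genes were measured, of which 9 were at least 2-fold lower, 1 was at least 2-fold higher and 18 lay within 2-fold. The lower ones included ABCA4 (4 of 4) at 26.3 and 7.43 FPKM, ABCA7 (2 of 3) at 11.2 and 2.96 and smchd1 at 8.34 and 3.30. All 5 ABCA genes picked on this chromosome were at least 2-fold lower, and whether they are separate genes was not tested. The bromodomain gene brd2a stood at 44.5 and 105 FPKM, and the ABC transporter gene abcg2a at 90.3 and 41.5.

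In the 3 patterns that follow, the test on histone genes was written before its result was seen, and the other 7 tests were chosen after it. The exocrine enzyme genes were lower together. The values argue against a library-wide difference in scaling as the cause, since the median of all genes was -0.01. The highest list median over 3 rescalings was -1.16. Each rescaling multiplied a whole library by a single factor and so could move the list only slightly. Other differences in composition were therefore not tested. Reads traded between near-identical enzyme genes of the list would leave their sum unchanged, while log2 of the summed FPKM was -1.26. Copies outside the list were not in this sum. Of these, zgc:136461, prss59.1 and prss59.2, named above, were lower as well, and trading with other copies was not tested. A general developmental delay might keep cell cycle genes high, yet their list median stood at the 65.6 percentile of random lists. That leaves a short delay open, since no time course was measured and the hatching enzyme genes were higher in the mutant library. Pool and genotype are confounded, so a lower acinar mass or enzyme output in the mutants is a hypothesis that these 2 libraries cannot separate from a difference between the pools.

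The erythrocyte genes were also lower together. Reads of ela2l counted for alas2 could not account for it, since they would touch only 1 of the 15 members. The median without alas2 was -0.65, below all random lists, but a median moves little when 1 member is left out. Trading of reads among the globin copies of the list leaves log2 of their summed FPKM at -0.98. Copies outside the list were not in this sum. A uniformly lower share of red blood cells was not decided. The 5 globin genes of the list differed among themselves by 1.19. That lay between 0.400, the span of 68% of single genes at their level, and 1.37, which spans 95% of those of at least 50 FPKM. Both widths describe single genes and not a range over 5 genes, and they come from different gene sets, so they cannot decide it. The scarce hbae5, added by Ensembl ID, was higher in the mutant library (0.912 to 4.60 FPKM). Fewer red cells in the mutant and fewer left in the larvae of that pool stay open. Lower globin transcription per cell stays open for the globin genes, but by itself it would not lower the other members. Each member other than the globins, as matched by symbol, was also lower. Among these were slc4a1a (30.2 to 11.9 FPKM), cahz (50.8 to 32.8) and fech (7.98 to 4.55). Not all of them stood out. The difference of tfr1a (6.94 to 5.48 FPKM, log2 -0.29) lay within the half-width of 0.37 that holds 68% of single genes of like abundance.

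Several structured RNAs were lower in the mutant library, rn7sk by 6.43-fold, Metazoa_SRP (summed over 74 rows) from 168 to 62.9 FPKM and zgc:158463, typed as ribosomal RNA in the GRCz12tu gene table, from 10394 to 1726 FPKM, but of all 17 measured, 7 were at least 2-fold lower, 7 at least 2-fold higher and 3 within 2-fold. Whether the change was limited to RNA polymerase III transcripts was not decided. Of 13 products of other polymerases, 10 differed at least 2-fold (4 lower, 6 higher), where random sets matched on mean FPKM reached at most 5. Only 6 of the 13 were above 0 in both libraries, and 3 of those 6 differed at least 2-fold. The random sets were not matched on gene length, so they do not show how much such short genes vary. Less carry-over of RNA without poly(A) tails may lower structured RNAs together with replication-dependent histones, but the 7 higher structured RNAs went the other way. The histone median was -0.58 at the 3.21 percentile. That value was just inside the random range and rests on 2 histone genes that went opposite ways, hist2h2l at 121 and 136 FPKM and hist2h3c at 16.7 and 6.07, while HIST1H4L, left out for its capitals, was listed at 0 in wild type and at 8.96 FPKM in the mutant. The bound set for this test was therefore too weak to exclude carry-over, and it cannot be told apart here from a difference that goes with genotype.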
